A study of Mus musculus with 11 samples.

How the data were processed

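RNA of cultured mouse oligodendrocyte lineage cells was measured on 11 Affymetrix Mouse Genome 430 2.0 arrays, 3 of knockout oligodendrocytes, 4 of control oligodendrocytes and 4 of progenitors kept in PDGF. Per the labels' protocols, cells of postnatal day 7 brains were depleted of microglia with the lectin BSL1 and then selected on plates coated with antibody to PDGFRα. They were grown in serum-free medium with 2% B-27. Total RNA was labelled from 1 µg with the Affymetrix assay that amplifies RNA in a pair of cycles. Per the submitters' processing notes, GCOS 1.3 and the MAS 5.0 algorithm gave a value per probe set, and each chip was scaled to a target of 500. The deposited values are MAS 5.0 signal intensity on a linear scale, per the labels. The mean signal without the top and bottom 2% of probe sets was 500 on every array, as that scaling requires. No counts or read depths exist for arrays, and their number limits the precision.

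Groups were taken from the sample titles. The comparisons, tests, gene lists, most alternatives and the rule for naming genes were chosen before the data were examined. Of 45101 probe sets, 34958 carried 1 gene symbol in the platform annotation, 932 carried several and 9211 were unnamed there. Symbols were matched to current ones through the Entrez identifier, for 34754 probe sets. Probe sets with several genes named none. A probe set was kept when it reached a signal of 200 on at least 3 arrays, whatever their group, which 18628 did, 17133 of them with 1 gene. Each gene was represented by its probe set with the highest mean log2 signal over all 11 arrays, which left 10070 genes. The 64 control probe sets of the array entered no comparison and served as measures of RNA quality.

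Signals were used as deposited, without further normalization, as log2 of the signal plus 16. A linear model with a mean per group was fitted to all 11 arrays in limma 3.58.1 under R 4.3.3, with a moderated variance that follows intensity. Contrasts gave knockout against control oligodendrocytes, control oligodendrocytes against progenitors and knockout oligodendrocytes against progenitors. P-values were adjusted by the Benjamini-Hochberg method over all genes of a comparison, with a threshold of 0.05, and for gene lists also over the list alone. The errors of log2 differences are the standard errors of that fit. Fold values are fitted differences. Where every array of the lower group lay under a signal of 100, the gene was given as at least N-fold against a floor of 100.

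Of 18 gene lists, 14 with at least 5 measured genes were tested with camera of limma at a preset correlation between genes of 0.01, adjusted over the lists. They held myelin proteins, sphingolipid synthesis, cholesterol synthesis, progenitor markers, markers of newly formed oligodendrocytes, lineage transcription factors other than Myrf, cell cycle, genes that oppose differentiation, node and adhesion genes, p53 and apoptosis, unfolded protein response, interferon response, and markers of astrocytes and of neurons. Markers of Schwann cells, and of smooth muscle, pericytes and meningeal fibroblasts, had too few measured genes and were counted by gene. Those of microglia and endothelium did not pass the filter. The lists held 339 genes, of which 317 had a probe set with their symbol.

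The genes named were a panel fixed for every comparison, the 12 largest rises and 12 largest falls between knockout and control oligodendrocytes, and the 8 largest of each in the other comparisons. For these the threshold had to be passed and the arrays of the 2 groups could not overlap. For each list up to 3 members past the threshold in each direction were added, and for markers of other cell types the 2 brightest. Of the 16 panel genes 15 were analysed, and 1 is not reported here. Not every gene that the rule selects is printed. The cartilage genes under other observations that the rule does not name, and Olig1, were named after their values were seen.

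The share of the differentiation change was the median change of the knockout arrays from progenitors over that of control oligodendrocytes, as a percent. Its genes, at least 4-fold changed, were chosen on replicates 1 and 2 of control oligodendrocytes and progenitors and measured on replicates 3 and 4, then the other way round, and averaged. The overlap of comparisons that share control arrays was repeated on separate control arrays, and the covariance of their log2 differences was also set against 20 simulations without effect.

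The pipeline was checked on simulated data with 10070 genes. At a log2 change of 2 it recovered 89%, 88% and 89% of changed genes in the 3 comparisons in the order above, and at a change of 1 it recovered 47%, 52% and 54%. False calls made up 9.33%, 4.76% and 2.72% of all calls. A shifted list was found and 0 null lists were called. Shares set at 40% came out as 40.2% for induced and 39.5% for repressed genes. The simulated noise was independent between genes and equal in all groups. On the real arrays the median SD of genes was 0.2 among knockout, 0.224 among control and 0.388 among progenitor arrays. The rates may therefore not hold there.

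The titles number the replicates within each group, and no label says what a number stands for. Deviations from the group means correlated between knockout and control arrays of the same number at r = 0.242, 0.241 and 0.214 across genes. These numbers were therefore taken as a possible pairing of the samples in that comparison. Knockout replicate 3 correlated more with control replicate 4, at 0.328, and at -0.343 and -0.334 with control replicates 1 and 2. Knockout replicates 1 and 2 correlated also with control replicates 2 and 1, at 0.14 and 0.159. With control replicates 3 and 4 their values were -0.2 to -0.109. The arrays thus form 2 sets, replicates 1 and 2 and the later ones, as much as pairs. The share and the overlap divided the control arrays along the same line. The pairing is an assumption that rests on the data and not on the labels, and the main fit did not use it.

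The alternatives were other pseudocounts, filters, normalizations, ways to combine probe sets, variance priors, array weights, a fit on the 2 compared groups, a replicate block, stricter thresholds, fry and an estimated correlation in place of camera's preset, other ways to compute the share, and leaving out each replicate. Added after seeing the data were fits with only progenitor replicates 2 and 3, and on knockout and control arrays without control replicate 3. Another division of the arrays for the share and a share without the astrocyte list were also added then. The replicate block was fitted on the 2 compared groups and on the replicate numbers found in both. For knockout against control it thus left out the progenitors and control replicate 4. Detection calls and raw image files were not used here. Plots were drawn with matplotlib 3.10.9.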

Results

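RNA of cultured mouse cells of the oligodendrocyte lineage, the cells that make myelin in the central nervous system, was measured on 11 Affymetrix mouse expression arrays. The cells were taken from brains at postnatal day 7 and selected by their PDGFRα surface protein after microglia had been removed. Knockout oligodendrocytes (n = 3) came from mice in which both copies of Myrf, labelled MRF, can be deleted by a Cre recombinase under the Olig2 gene. Control oligodendrocytes (n = 4) came from littermates with 1 such copy. Both were grown for 4 days with the thyroid hormone T3 at 40 ng/ml and without PDGF, which starts differentiation. Progenitors (n = 4) stayed for 6 days in PDGF at 10 ng/ml, and the labels give no genotype for them beyond the word control. Each array had a trimmed mean signal of 500, the authors' scaling target, and a median of 60.5 to 80.4. Between 15100 and 17130 of the 45101 probe sets per array reached a signal of 200. After the filter on dim probe sets, 10070 genes were tested.

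Replicates correlated across genes, which are not independent replicates, at r = 0.962 to 0.973 among knockout arrays, 0.936 to 0.977 among control arrays and 0.844 to 0.975 among progenitor arrays. Progenitor replicate 2 stood apart from its group, with a cell cycle gene level of 10.3 on the log2 scale against 12.3 to 12.5 on the other progenitor arrays. The ratio of Gapdh signal at the 5′ end to that at the 3′ end, a sign of RNA length, was 1.26 to 1.41 on the oligodendrocyte arrays. It was 0.332, 1.23, 1.15 and 0.12 on progenitor replicates 1 to 4. The same ratios of the spiked-in bacterial transcripts dap and thr, which follow the labelling, were 0.331 to 0.495 on the oligodendrocyte arrays, 0.375 and 0.36 on progenitor replicate 2, 0.223 and 0.195 on replicate 3 and 0.0251 to 0.103 on replicates 1 and 4. The labels do not say whether replicates were separate cultures or animals, so the p-values measure only the spread between these samples, which may be technical. The number of arrays limits the precision of every value.

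Knockout and control oligodendrocytes were compared to find the genes that depend on Myrf in cells kept under differentiation conditions. The targeted gene, Myrf, gave signals of 2849, 1904 and 2223 on knockout replicates 1 to 3, and of 6215 to 7517 on the 4 control arrays. On progenitor replicates 1 to 4 its signals were 752.1, 6848, 1135 and 970.5. The log2 difference between knockout and control was -1.58 ± 0.57 (SE), and the 2 groups of arrays did not overlap. In the limma fit of all 11 arrays its adjusted p was 0.127. That fit takes the spread of a gene from all 3 groups, so the wide range of Myrf among progenitors enters it. The adjusted p was 0.000257 when only the 2 compared groups were fitted and 0.000892 with replicate number as a block, within a range of 0.000257 to 0.353 over all alternatives. A single probe set named Myrf, and where it lies relative to the deleted part was not examined here, so this value is a limited check of the genotype labels.

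**Figure D1:**
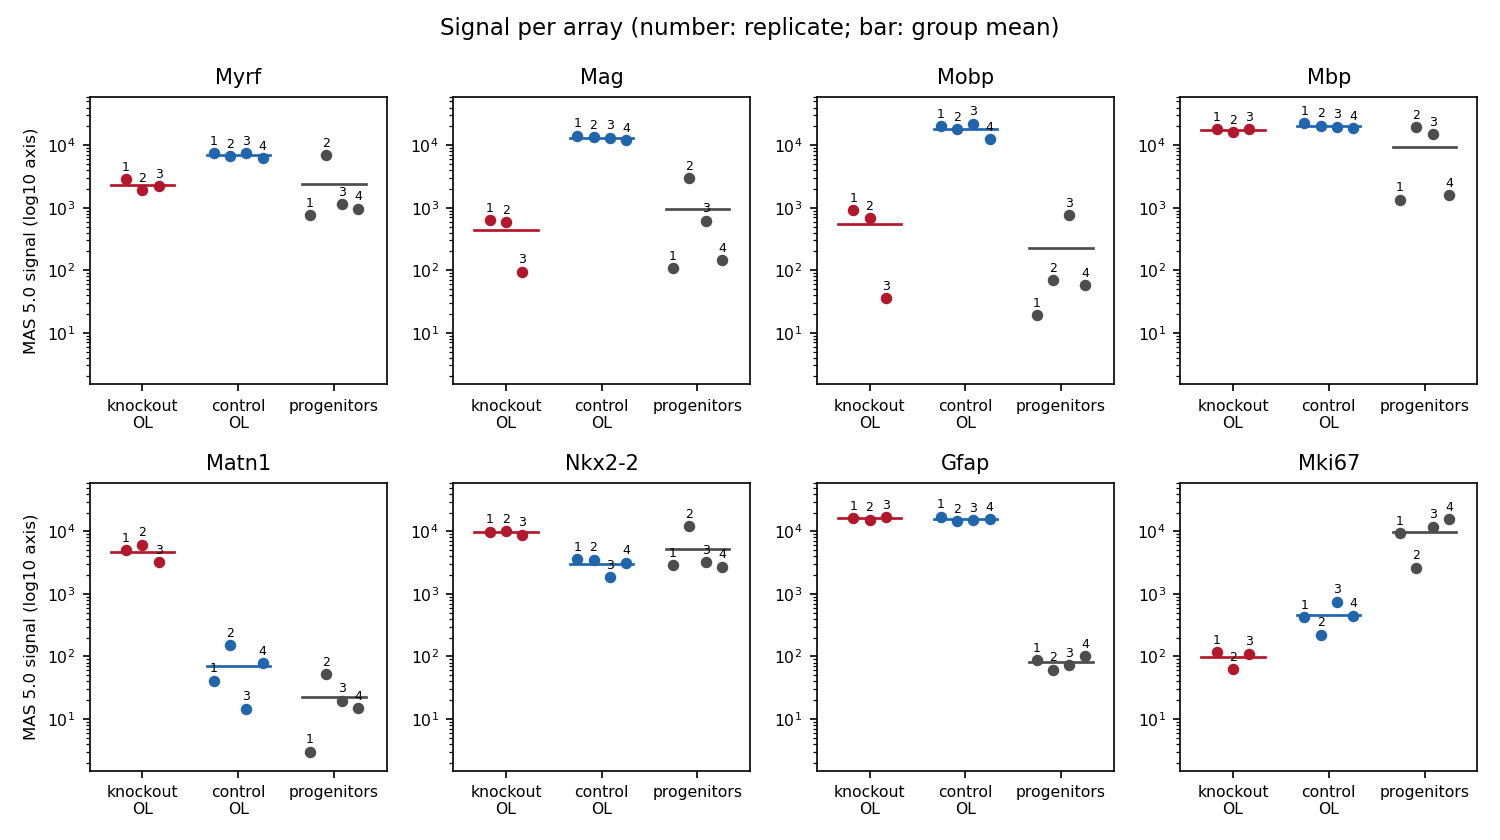
Signal of 8 genes on each of the 11 arrays, on a log10 axis in MAS 5.0 signal units, where each point is an array, each bar the mean of its group and each number beside a point the replicate. Mag lies at 11997 or more on the 4 control arrays and at 639 or less on the 3 knockout arrays, Matn1 shows the opposite order, Mbp is near its control level in the knockout arrays, and Gfap is at 14658 or more on all oligodendrocyte arrays.

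Myelin protein genes formed the group with the deepest falls in the knockout cultures. Tppp, which promotes microtubule assembly, had a mean signal of 143 ± 107 (SD, n = 3) against 7388 ± 1853 (SD, n = 4) in control cultures, 59.5-fold lower (limma, adjusted p = 0.00014). Mobp, a protein of compact myelin, was 55.5-fold lower at 541 ± 451 against 18181 ± 4154 (adjusted p = 0.00493). Mag, which binds myelin to the axon, was 37.2-fold lower at 442 ± 301 against 13198 ± 925 (adjusted p = 0.00481). Mog, a protein of the outer myelin surface, was at least 14.7-fold lower. Without knockout replicate 3 the folds were 32.9 for Tppp, 22.2 for Mobp and 20.9 for Mag, and without knockout replicate 1 that of Mobp was 93.9. The bound of Mog was 9.59-fold without control replicate 3 and 22.7-fold without control replicate 4. Of 30 measured myelin protein genes 17 fell, 20 when adjusted over the list alone, and none rose at an unadjusted p under 0.05. The list's median log2 difference was -1.74 (camera, adjusted p = 1.55e-14, adjusted p = 0.105 with an estimated correlation, and fry 0.00174). Other prominent myelin genes had smaller differences, which did not pass. Mbp, which compacts the myelin membrane, had 17329 ± 1201 against 20308 ± 1530.5, a log2 difference of -0.23 with an adjusted p of 0.911. The log2 differences were -0.22 for Cnp (adjusted p = 0.673), -0.33 for Cldn11 (0.655), -0.82 for the galactolipid enzyme Ugt8a (0.305) and -1.92 for Opalin (0.0606). Mbp and Cnp lay near the highest signal of any probe set on the oligodendrocyte arrays, 22057 to 26673, so a difference compressed at the top of the scale is not excluded. Ugt8a had an adjusted p of 0.00133 when only the 2 compared groups were fitted and 0.00191 with replicate number as a block, within 0.00133 to 0.604 over its alternatives. Opalin had 0.000513 and 0.000796, within 0.000513 to 0.186.

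**Figure D2:**
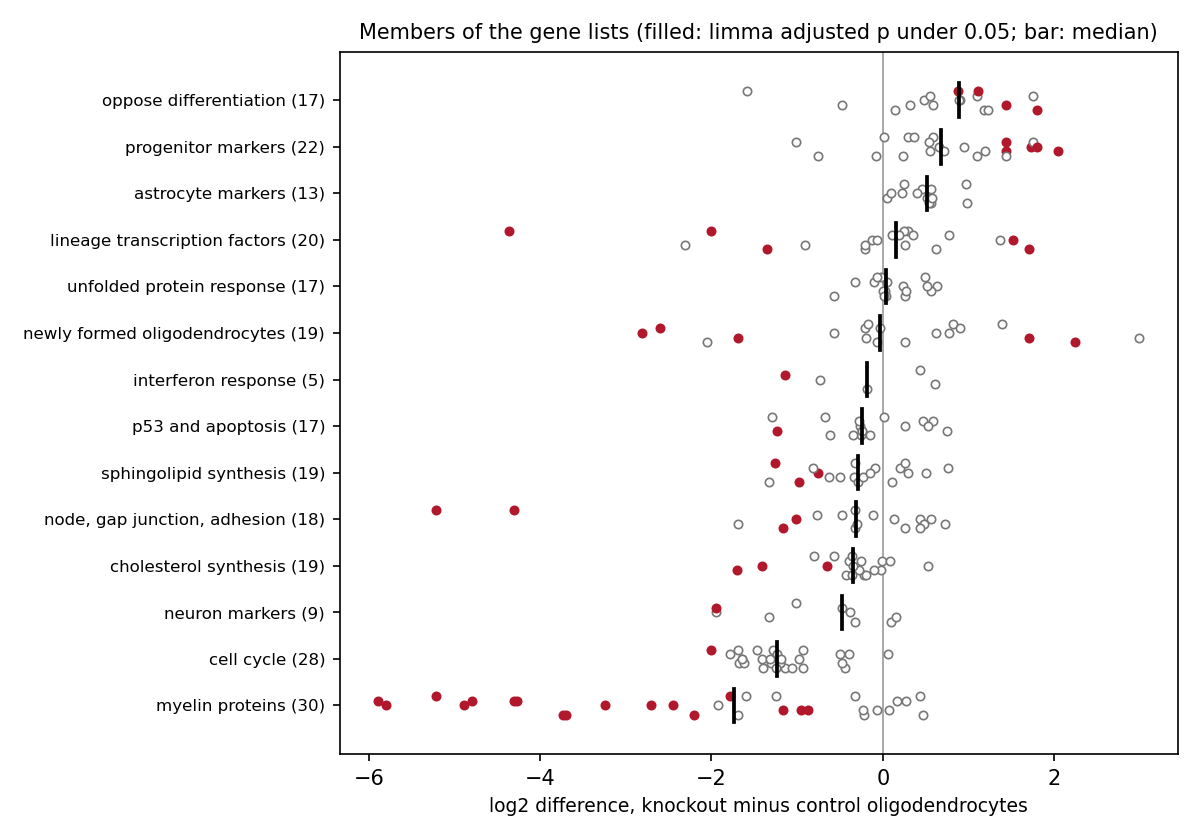
Log2 difference of knockout minus control oligodendrocytes for each measured gene of 14 gene lists, where each point is a gene, filled where limma's adjusted p was under 0.05, and each bar is the list's median. The myelin protein list has a median of -1.74 and the list of genes that oppose differentiation one of 0.89, while the stress list lies around 0.04.

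Further genes fell steeply beside the myelin list. Ermn, a cytoskeletal protein of oligodendrocytes, was at least 18.6-fold lower, Tgfbi at least 17.3-fold, Tmem151a at least 11.6-fold and Rab33a 20.7-fold. St18, a zinc finger transcription factor, was at least 7.38-fold lower, Ano4 at least 6.56-fold, the activity-regulated gene Arc at least 6.13-fold and the gap junction gene Gjb1 at least 6.12-fold. Matn1, a cartilage matrix protein, rose most, to 4749 ± 1466 from 71.5 ± 59.4, 63.4-fold (limma, adjusted p = 8.06e-05). Rnf128, a ubiquitin ligase, was 16.9-fold higher, the cartilage collagen Col2a1 15.1-fold, Fam163a 11.7-fold, the adhesion molecule L1cam 9.11-fold, the proteoglycan Acan 9.08-fold and Bche, a cholinesterase, 8.47-fold. Arhgap24 was at least 12.6-fold higher, Chodl at least 9.40-fold, Plekhd1 at least 8.27-fold, Slc27a3 at least 4.82-fold and Eya2 at least 4.35-fold. For all of these the arrays of the 2 groups did not overlap. The control means of Matn1 and Acan lay under a signal of 100, and against that floor their folds were 45.9 and 6.14. Without control replicate 3 the fold of Col2a1 was 7.62 and the bound of Gjb1 3.46-fold, and without knockout replicate 3 the bound of Chodl was 14.8-fold.

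Progenitor markers were higher in the knockout cultures as a list, with 5 of 22 measured genes rising, 5 when adjusted over the list alone. Over the 18 alternatives 2 to 13 rose and 0 to 1 fell. Vcan, a matrix proteoglycan, was 4.12-fold higher (limma, adjusted p = 0.00172), the glutamate receptor subunit Gria3 3.31-fold (0.00491) and the transcription factor Sox5 3.47-fold (0.0126, and 0.0684 without knockout replicate 3). The list's median log2 difference was 0.68 (camera, adjusted p = 0.000246, and adjusted p = 0.255 with an estimated correlation). The progenitor receptor Pdgfra, at -0.75 (adjusted p = 0.238), and the proteoglycan Cspg4, at 0.29 (adjusted p = 0.746), did not pass. In progenitors Vcan and Gria3 had means of 1555 and 1247, above their control means of 652.5 and 364.7, while Sox5 had 219.7 against 208.5. The list passed neither from progenitors to control (camera, adjusted p = 0.336) nor to knockout oligodendrocytes (0.474). Its rise is thus no measure of kept progenitor identity. The astrocyte list was higher in the knockout cultures too, with a median of 0.52, and control replicate 3 was the lowest oligodendrocyte array for both lists, at 9.95 and 11.86 on the log2 scale. The lists share no gene, but some progenitor markers, such as Id4, are also expressed by astrocytes. Genes of pathways that oppose differentiation were also higher, in a list that shares Hes5, Id2, Id4, Sox5 and Sox6 with the progenitor markers. Of the 17 measured, 4 rose, and 0 to 10 did over the alternatives. Adjusted over the list alone 7 rose and 1 fell, with a median of 0.89 (camera, adjusted p = 0.000982, and adjusted p = 0.105 with an estimated correlation). Among them, Sox6 was 2.72-fold higher (adjusted p = 0.0368), but its adjusted p was 0.0751 to 0.16 without any one knockout array or control replicate 1 or 3.

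Lineage transcription factors split, with 2 of 20 higher and 3 lower, and adjusted over the list alone 2 higher and 4 lower. Their median log2 difference was 0.15 and their mean -0.21, opposite in sign (camera, adjusted p = 0.474). Nkx2-2 was 3.26-fold higher at 9644 ± 662 against 3033 ± 797 (limma, adjusted p = 0.0354), and 0.0555 to 0.13 without any single one of the 7 arrays. Zfp536 was 4.01-fold lower (limma, adjusted p = 0.00907, but 0.0607 without knockout replicate 2 and 0.0517 without replicate 3, and 6.27-fold without replicate 1). The lineage factors Olig2 and Sox10 had log2 differences of 0.35 and 0.26, with adjusted p-values of 0.439 and 0.324. With replicate number as a block Olig2 reached 0.0425, within 0.0425 to 0.649 over its alternatives. Among 19 markers of newly formed oligodendrocytes, 2 rose and 3 fell, the same numbers as when adjusted over the list alone, with a median of -0.03 (camera, adjusted p = 0.578). Here Rras2, a small GTPase, was 6.05-fold lower (adjusted p = 3.49e-05) and Cemip2 7.04-fold lower (adjusted p = 0.00522).

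Cell cycle genes had a median log2 difference of -1.24 over 28 measured genes (camera, adjusted p = 8.3e-09, and adjusted p = 0.397 with an estimated correlation). Control replicate 3 had the highest level of this list among control arrays, 9.847 on the log2 scale against 8.256 to 8.997. Only Mki67, a marker of dividing cells, fell by itself, 4.01-fold (limma, adjusted p = 0.0443), and 0 genes did when adjusted over the list alone, though 19 were lower at an unadjusted p under 0.05. With replicate number as a block 16 of them fell. The adjusted p of Mki67 was 0.084 to 0.19 without any one array other than control replicate 2. Lipid genes moved less. In cholesterol synthesis 3 of 19 genes fell, 3 when adjusted over the list alone, with a median of -0.35 (camera, adjusted p = 0.000982, and adjusted p = 0.286 with an estimated correlation). The sterol isomerase Ebp was 2.65-fold lower (limma, adjusted p = 0.00399). In sphingolipid synthesis 3 of 19 genes fell, among them Elovl6, 2.39-fold, and the ceramide synthase Cers2, 1.97-fold. Adjusted over the list alone, 3 fell and 1 rose, and over the 18 alternatives 2 to 9 fell and 0 to 2 rose. That list's median was -0.29 (camera, adjusted p = 0.0368, and adjusted p = 0.397 with an estimated correlation), and the call ended under 6 of 18 alternatives, with an adjusted p of 0.0931 without knockout replicate 1, 0.0517 without control replicate 1 and at most 0.131, under quantile normalization. Of 18 node, gap junction and adhesion genes 4 fell, including Mag and Gjb1. Both are also on the myelin list, as are Nfasc, Cntn1, Gjc3 and Cldn11, so the 2 lists are not independent. Adjusted over the list alone, 6 fell and 1 rose. Their median was -0.31 (camera, adjusted p = 0.0333, 0.0583 with replicate number as a block, and adjusted p = 0.435 with an estimated correlation). The call also ended with a stricter filter on dim probe sets (adjusted p = 0.119) and under quantile normalization (0.0931).

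Stress lists did not pass. Of 17 p53 and apoptosis genes 1 fell, Phlda3 (camera for the list, adjusted p = 0.219), and its adjusted p of 0.0402 lay between 0.0583 and 0.151 without any single array other than control replicate 4. None of 17 unfolded protein response genes passed limma's threshold, and 4 had an unadjusted p under 0.05 (camera for the list, adjusted p = 0.474, and fry 0.13). Over the alternatives 0 to 4 of these genes rose and 0 to 1 fell. Among 5 interferon genes H2-K1 was 2.21-fold lower (limma, adjusted p = 0.00815; camera for the list, adjusted p = 0.219). The direction of H2-K1 is not settled, since another of its probe sets was the brightest with a pseudocount of 64 or quantile normalization and gave log2 differences of 0.18 and 0.17.

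Markers of other cell types were measured in the same arrays. Astrocyte genes were high in both kinds of oligodendrocyte culture, with Gfap, an astrocyte filament protein, at 16237 ± 792 in knockout and 15744 ± 1100 in control cultures against 80.7 ± 16.8 in progenitors. Between knockout and control 0 of the 13 astrocyte genes passed limma's threshold, 0 when adjusted over the list alone, and 3 were higher at an unadjusted p under 0.05. With replicate number as a block 6 of them rose, among them S100b (limma, adjusted p = 0.0149, within 0.0149 to 0.718 over its alternatives). As a list they were higher in the knockout, with a median of 0.52 (camera, adjusted p = 0.0199, 0.0548 without knockout replicate 3, adjusted p = 0.397 with an estimated correlation, and fry 0.0568). Of 9 neuronal genes 1 fell, Nefm, at least 2.80-fold, with a median of -0.48 (camera, adjusted p = 0.0155, and adjusted p = 0.105 with an estimated correlation). The limma call of Nefm at 0.0409 ended, at 0.062 to 0.142, without any one array other than control replicate 1 or 3. Among 3 smooth muscle and pericyte genes Tagln rose 6.00-fold and Myl9 3.36-fold. Their adjusted p-values, 0.0188 and 0.0386, became 0.0575 to 0.095 for Tagln and 0.0691 to 0.168 for Myl9 without any one knockout array, and 0.0597 for Myl9 without control replicate 4. The fold of Tagln was 3.71 without control replicate 3. The third gene, Acta2, passed under none of its 18 alternatives, with adjusted p-values of 0.0658 to 0.353. Of the same list, the fibroblast genes Col1a2 and Col3a1 missed the filter. Their means were 341.3 and 381.2 in knockout against 88.98 and 86.48 in control cultures, while Rgs5 and Vtn, also under the filter, were not higher. In the 2 alternatives that measured at least 5 genes of this list, it was higher in the knockout (camera, adjusted p = 0.00321 and 0.0234). Of 3 Schwann cell genes 0 passed limma's threshold and 1 was lower at an unadjusted p under 0.05. No microglial or endothelial marker passed the filter, and the highest signals of those genes on any array were 413.4 and 282.8.

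In all, 758 of 10070 genes differed between knockout and control cultures (limma, adjusted p under 0.05), 367 higher and 391 lower. Of these, 572 differed at least 2-fold, and 61 were lower and 12 higher by at least 8-fold. The 2 groups of arrays did not overlap for 31.6% of all genes, where chance gives 5.71%. With replicate number as a block, which also left out the progenitors and control replicate 4, the count was 2238. It was 1587 when only the 2 compared groups were fitted, which leaves out the wider spread among progenitors. It was 411, 374 and 430 without knockout replicates 1, 2 and 3, and 481 and 489 without control replicates 1 and 3.

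The genes lower in the knockout cultures were set against the change from progenitors to control oligodendrocytes. Of the 391 lower genes, 287 (73.4%) were higher in control oligodendrocytes than in progenitors and 23 were lower. Independent lists of these sizes would share 95.3 and 115.7 genes. Because both comparisons use the control arrays, the count was repeated on separate control arrays. It was 263 with control replicates 1 and 2 for the knockout comparison and 3 and 4 for the progenitor comparison, and 234 the other way round. The genes lower in both comparisons, 23 with shared controls, numbered 19 in the first arrangement and 125 in the second. Of the 367 genes higher in the knockout cultures, 144 (39.2%) were lower in control oligodendrocytes than in progenitors, against 108.6 for independent lists, and 84 were higher, against 89.4. Those counts were 117 and 57 in the first arrangement of separate control arrays and 78 and 140 in the second. Over all genes the covariance of the 2 log2 differences was -0.0976, against -0.0477 in the simulations, and -0.164 and 0.0413 on separate control arrays.

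Control oligodendrocytes were compared with progenitors to give the change of differentiation in cells that keep Myrf. The groups also differed in T3, PDGF and days in culture. On the 4 progenitor arrays the 5′ probe set for 18S ribosomal RNA gave 2109.7 to 7805.8, against at most 130.4 on oligodendrocyte arrays. The dap spike-in gave 1934.4 to 5795.1 at its 3′ end, against at least 6033. In both comparisons with progenitors, the genes counted therefore cannot be divided between differentiation and labelling or processing. Myelin genes rose, cell cycle genes and the progenitor genes Cspg4 and Pdgfra fell, and astrocyte genes had the highest median rise of the 14 tested lists. Of 30 myelin protein genes 23 rose and 3 fell, the same numbers as adjusted over the list alone, with a median log2 difference of 3.26 (camera, adjusted p = 6.16e-08, and adjusted p = 0.174 with an estimated correlation). Mobp rose 156-fold (limma, adjusted p = 0.000101), Mal, a myelin proteolipid, at least 47.9-fold, and Mag 30.0-fold (adjusted p = 0.000684). Without progenitor replicate 3 Mobp was at least 178-fold higher, and the fold of Mag was 19.6 and 56.6 without replicates 1 and 2. Mbp rose 4.04-fold (limma, adjusted p = 0.0345), with signals of 1338, 19380, 15042 and 1587 on progenitor replicates 1 to 4. Its adjusted p was 0.0596 to 0.105 without any one array other than progenitor replicate 2 or 3, and 0.139 with only progenitor replicates 2 and 3. Myrf rose 4.43-fold (limma, adjusted p = 0.00521, and 0.075 with only progenitor replicates 2 and 3), although progenitor replicate 2 reached 6848. Without that replicate the folds were 7.25 for Myrf, 6.34 for Mbp and 11.7 for Opalin, and without replicate 1 that of Mbp was 2.61. Opalin rose 7.78-fold, Cldn11 4.17-fold and Ugt8a 3.14-fold, while Cnp, at 0.37, did not pass (adjusted p = 0.187). Cnp passed at 1.63 with the mean of its probe sets (adjusted p = 0.00729), 1.8 without shared probe sets (0.00708), 0.81 under quantile normalization (0.00314) and 0.58 without progenitor replicate 2 (0.0229), and was at -0.0758 with only progenitor replicates 2 and 3.

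All 28 cell cycle genes fell, over all genes and over the list alone, with a median of -2.99 (camera, adjusted p = 6.69e-10, and adjusted p = 0.422 with an estimated correlation). Mki67 was 18.8-fold lower (limma, adjusted p = 4.77e-05), the mitotic kinase Bub1 12.9-fold and Cdc20 11.7-fold. Of 22 progenitor markers 8 fell and 5 rose, as they did over the list alone (camera, adjusted p = 0.336). Cspg4 was 21.4-fold lower (limma, adjusted p = 4.47e-06) and Pdgfra 4.95-fold lower, while Matn4 was 40.4-fold higher, 30.1-fold against a floor of 100, and Id4 25.5-fold. The largest other falls were those of Plppr1, 16.9-fold, the integrin Itga8, 16.4-fold, Kif2c, 15.3-fold, Lrr1, 15.2-fold, Cenpe, 15.1-fold, and Rpgrip1, 14.7-fold. Without progenitor replicate 2 the folds were 33.9 for Itga8, 23.9 for Kif2c, 25.3 for Lrr1 and 22.6 for Cenpe, and without control replicate 3 that of Rpgrip1 was 7.79.

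All 13 astrocyte genes rose, over all genes and over the list alone, with a median of 4.49, or 4.30 with dim genes at their bound (camera, adjusted p = 1.51e-12, and adjusted p = 0.0459 with an estimated correlation). Gfap was 165-fold higher (limma, adjusted p = 3.1e-11), the water channel Aqp4 at least 97.2-fold and the gap junction gene Gja1 at least 93.3-fold. The other large rises were those of the lipoprotein Apoe, 226-fold, the sphingosine phosphate receptor S1pr3, at least 68.1-fold, Mlc1, at least 50.7-fold, and Tmem125, at least 34.2-fold. Progenitor means under 100 underlie the folds of Gfap and Apoe, which were 157 and 144 against that floor. All 3 measured smooth muscle and pericyte genes rose, with Myl9 at least 5.12-fold. Of 9 neuronal genes 3 rose and 2 fell (camera, adjusted p = 0.715), and of 3 Schwann cell genes 1 fell.

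Lipid and adhesion genes rose in part. Of 19 sphingolipid genes 15 rose, 15 over the list alone, with a median of 1.29 (camera, adjusted p = 2.8e-05, and adjusted p = 0.174 with an estimated correlation), led by the fatty acid hydroxylase Fa2h, 8.92-fold, or 16.1-fold without progenitor replicate 2. In cholesterol synthesis 11 of 19 genes fell and 2 rose, 11 and 2 over the list alone, with a median of -0.59 (camera, adjusted p = 0.0329, and adjusted p = 0.519 with an estimated correlation). That call held in 15 of 19 alternatives. Among others, it ended without progenitor replicate 2 (adjusted p = 0.203) or control replicate 4 (0.0642) and under quantile normalization (0.0617). Tm7sf2, a sterol reductase, was 3.17-fold lower and Ebp 1.70-fold higher. Of 18 node, gap junction and adhesion genes 15 rose and 2 fell, 15 and 2 over the list alone, with a median of 1.81 (camera, adjusted p = 0.000174, and adjusted p = 0.233 with an estimated correlation). All 5 interferon genes rose, over all genes and over the list alone, with a median of 1.41 (camera, adjusted p = 0.0028, and adjusted p = 0.175 with an estimated correlation).

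Of 19 markers of newly formed oligodendrocytes 9 rose and 1 fell, 9 and 1 over the list alone, with a median of 1.34 (camera, adjusted p = 0.023, and adjusted p = 0.575 with an estimated correlation). The call ended without progenitor replicate 1 (adjusted p = 0.0652) and with only progenitor replicates 2 and 3 (0.223). Tmem163 was 21.5-fold higher and the phosphodiesterase Enpp6 22.2-fold, with a signal of 6561 on progenitor replicate 2 and of 45.5 to 333.9 on the others. With only progenitor replicates 2 and 3, Enpp6 had an adjusted p of 0.0827. Its fold was 13.2, 61.3 and 12.9 without progenitor replicates 1, 2 and 4, and that of Tmem163 was 12.4 and 44.8 without replicates 1 and 2. Of 20 lineage transcription factors 7 rose and 6 fell (camera, adjusted p = 0.556). Klf9 was 18.9-fold and Nkx6-2 11.8-fold higher, the latter 8.29-fold against a floor of 100. Olig2 was 1.59-fold lower (limma, adjusted p = 0.022), a call that ended without control replicate 2 (0.0597) and under quantile normalization (0.0515). Sox10 was 1.33-fold lower (adjusted p = 0.0223), while another of its probe sets was called in the opposite direction and the mean of its probe sets had a log2 difference of 0.65. The call of Sox10 also ended, at 0.051 to 0.068, without control replicate 2 or 3 or progenitor replicate 2 or 4. Genes that oppose differentiation (6 of 17 rose and 2 fell), p53 and apoptosis genes (4 of 17 rose and 5 fell) and unfolded protein response genes (3 of 17 rose and 6 fell) did not pass as lists, with camera's adjusted p-values of 0.331, 0.953 and 0.556.

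In all, 5433 of 10070 genes differed (limma, adjusted p under 0.05), 2454 higher and 2979 lower in control oligodendrocytes, 2908 of them at least 2-fold. The 2 groups of arrays did not overlap for 43.8% of genes, where chance gives 2.86%. With only progenitor replicates 2 and 3, whose 5′ Gapdh signal was not lost, 4288 genes differed and 3830 of these were among the 5433. Scaling the arrays to one median shifted the median log2 difference of all genes to -0.14, and values near 0 are to be read against that shift.

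**Figure D3:**
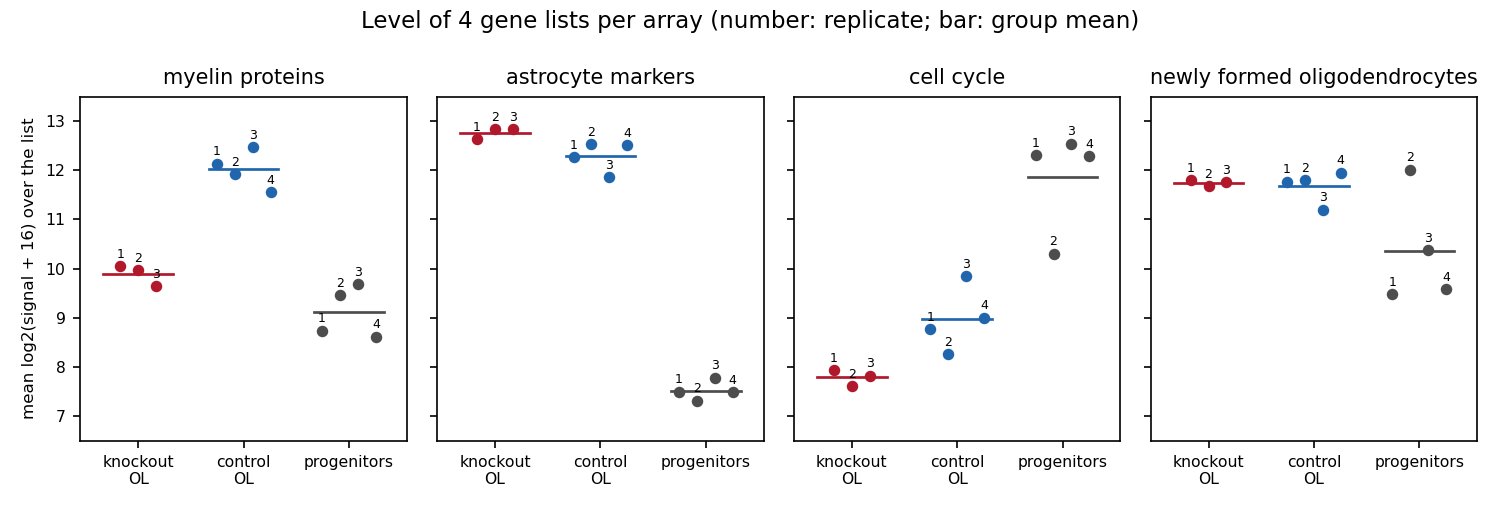
Mean log2 signal of 4 gene lists on each of the 11 arrays, where each point is an array, each bar the mean of its group and each number beside a point the replicate. Progenitor replicate 2 has a cell cycle level of 10.3 against 12.3 to 12.5 on the other progenitor arrays and a level of 12.01 for markers of newly formed oligodendrocytes against 9.47 to 10.4, while its astrocyte level of 7.31 is below the 7.48 to 7.78 of the others.

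Knockout oligodendrocytes were compared with progenitors to show how far the knockout cultures still moved under differentiation conditions. Cell cycle genes fell, as did the progenitor genes Cspg4 and Pdgfra, and astrocyte genes rose, while single myelin genes differed in whether they rose. All 28 cell cycle genes fell, over all genes and over the list alone, with a median of -4.28, or -4.19 with dim genes at their bound (camera, adjusted p = 1.32e-13, and adjusted p = 0.329 with an estimated correlation). Mki67 was 75.3-fold lower (limma, adjusted p = 5.15e-06), Bub1 at least 25.7-fold, Aspm at least 24.4-fold, Rad51ap1 at least 21.6-fold and Melk at least 17.8-fold. Cenpe was at least 17.2-fold lower, Lrr1 at least 13.2-fold and Sgo1 at least 8.14-fold. Without progenitor replicate 2 the bounds were 37.0-fold for Rad51ap1, 27.7-fold for Melk, 25.9-fold for Cenpe and 22.3-fold for Lrr1. Cspg4 fell 17.5-fold and Pdgfra 8.35-fold.

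Of 30 myelin protein genes 11 rose and 3 fell, 11 and 3 over the list alone, with a median of 0.70 (camera, adjusted p = 0.0934, but 0.0418 without progenitor replicate 3 and 0.018 under quantile normalization). Gjc3, a gap junction gene, rose 17.8-fold, Car2, a carbonic anhydrase, 7.54-fold, and Cldn11 3.32-fold (limma, adjusted p = 0.00196). Without progenitor replicate 4 Gjc3 was 11.7-fold higher. Mag, at -0.31 (adjusted p = 0.797), Mobp, at 1.49 (0.248), Mbp, at 1.79 (0.0767), and Cnp, at 0.16 (0.621), did not pass. Mag turned to 0.52 without knockout replicate 3 and to 0.60 without progenitor replicate 2. Mog lay under a signal of 100 on every knockout and progenitor array, so no difference is given for it. Without progenitor replicate 3 Mobp had an adjusted p of 0.0395 and Mbp one of 0.0273, and without knockout replicate 3 Mobp had one of 0.0275. Without progenitor replicate 2 the adjusted p was 0.00646 for Mbp, 0.000161 for Myrf, 0.00103 for Ugt8a and 0.00192 for Opalin, against 0.0767, 0.431, 0.13 and 0.142 with all arrays. Cnp, which turned to -0.09 without progenitor replicate 1, passed at 0.73 under quantile normalization (adjusted p = 0.00898), 1.28 with the mean of its probe sets (0.0353) and 1.42 without shared probe sets (0.0347).

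Astrocyte genes rose in 13 of 13 cases, over all genes and over the list alone, with a median of 5.05, or 4.84 with dim genes at their bound (camera, adjusted p = 2.33e-13, and adjusted p = 0.0408 with an estimated correlation). Gfap was 170-fold higher (limma, adjusted p = 5.09e-11), Aqp4 at least 133-fold, Gja1 at least 99.3-fold, Apoe 258-fold, S1pr3 at least 79.1-fold and Mlc1 at least 73.7-fold. Igfbp5 was at least 52.5-fold and Pla2g7 at least 31.6-fold higher. Against a floor of 100 the folds of Gfap and Apoe were 162 and 164. The 3 measured smooth muscle and pericyte genes rose, with Tagln at least 24.3-fold. Of 9 neuronal genes 2 rose and 5 fell (camera, adjusted p = 0.591), and of 3 Schwann cell genes 1 rose and 2 fell.

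Genes that oppose differentiation were higher, with 7 of 17 rising and 1 falling, 7 and 1 over the list alone, and a median of 0.78 (camera, adjusted p = 0.0105, and adjusted p = 0.283 with an estimated correlation). Id4, an inhibitor of helix-loop-helix factors, was 54.7-fold higher. Among 19 markers of newly formed oligodendrocytes 7 rose, 6 over the list alone, with a median of 0.63 (camera, adjusted p = 0.0689, but 0.00127 without progenitor replicate 2, 0.013 under quantile normalization and under 0.05 in 2 further alternatives). The growth factor Bmp4 was 39.2-fold higher (limma, adjusted p = 0.00457), at 4679 to 6835 on knockout arrays, 433.1 to 1268 on control arrays, 3614 on progenitor replicate 2 and 10.5 to 120.5 on the other progenitor arrays. Without progenitor replicates 1, 2 and 4 in turn its fold was 22.0, 113 and 25.1. Progenitor markers (8 of 22 rose and 5 fell) and lineage transcription factors (5 of 20 rose and 5 fell) did not pass as lists, with camera's adjusted p-values of 0.474 and 0.793. Nkx2-2 was 2.29-fold higher (limma, adjusted p = 0.0389), with 0.0735 to 0.101 without any one array other than progenitor replicate 2, and 0.312 with only progenitor replicates 2 and 3. Olig2, at -0.32 (adjusted p = 0.274), and Sox10, at -0.14 (0.424), did not pass, and quantile normalization turned them to 0.01 and 0.21.

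Of 19 sphingolipid genes 11 rose and 1 fell, 11 and 1 over the list alone, with a median of 0.90 (camera, adjusted p = 0.00195, and adjusted p = 0.283 with an estimated correlation). In cholesterol synthesis 14 of 19 genes fell and 1 rose, 14 and 1 over the list alone, with a median of -0.82 (camera, adjusted p = 0.000372, and adjusted p = 0.283 with an estimated correlation). Of 18 node, gap junction and adhesion genes 13 rose and 2 fell, 13 and 2 over the list alone, with a median of 1.56 (camera, adjusted p = 0.0113, and adjusted p = 0.403 with an estimated correlation). Interferon genes (3 of 5 rose, 4 over the list alone), p53 and apoptosis genes (4 of 17 rose and 4 fell) and unfolded protein response genes (4 of 17 rose and 4 fell) did not pass as lists, with camera's adjusted p-values of 0.0526, 0.641 and 0.905. The interferon list passed without knockout replicate 1 (adjusted p = 0.031) and without progenitor replicate 1 (0.0469) or 3 (0.0397), and under 6 other alternatives.

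In all, 5098 of 10070 genes differed (limma, adjusted p under 0.05), 2400 higher and 2698 lower in knockout oligodendrocytes, 2971 of them at least 2-fold. The 2 groups of arrays did not overlap for 49.9% of genes, where chance gives 5.71%. With only progenitor replicates 2 and 3, 4175 genes differed and 3734 of these were among the 5098.

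The share of the change from progenitors to control oligodendrocytes that the knockout cultures also showed was measured on genes that changed at least 4-fold between those groups. These genes were chosen on some of the control and progenitor arrays and measured on the others. Induced genes, 378 and 617 in the 2 selections, reached 92.7% ± 5.48 (SD, n = 3) of the control change, with 88.3%, 98.9% and 90.9% on knockout replicates 1 to 3. Repressed genes, 83 and 409 in the 2 selections, reached 94.1% ± 1.93 (SD, n = 3). By list, the median change of myelin protein genes from the progenitor mean was 0.88 ± 0.43 (SD over the 3 knockout arrays) on the log2 scale, against 3.26 in control oligodendrocytes. Astrocyte genes changed by 4.98 ± 0.30 against 4.49, and cell cycle genes by -4.25 ± 0.05 against -2.99. Markers of newly formed oligodendrocytes changed by 0.78 ± 0.07 against 1.34. No test was applied to these shares. Both kinds of oligodendrocyte culture also differed from the progenitors in T3, PDGF, days in culture, labelling measures and astrocyte genes. All such common differences count in the share, so it is no measure of differentiation alone.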

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

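The tests of explanations for the 3 patterns weighed here were chosen only after the results had been seen, while the counts over other splits of the arrays were planned. Chance puts a sample this far from its group in about 1 of 20 groups, and of 238 groups examined, of 97 genes, the gene lists and quality measures, 26 had such a sample, where 11.9 would come by chance. Of the 26, 17 were progenitor replicate 2 and 6 were control oligodendrocyte replicate 3. The genes are not independent.

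Myelin genes were lower in the knockout cultures, with a median log2 difference of -1.74 over the list. Fewer cells of the oligodendrocyte lineage would lower Olig1, Olig2 and Sox10 too, but their mean log2 difference was 0.16 with an SD of 0.26 over the 3 genes, which argues against it as the whole cause. Control replicate 3 alone is not the cause either, since the median was -1.72 without it. The loss of Myrf, which the design names, stays open as an untested candidate explanation, as does any difference between the cultures that the labels do not record.

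Astrocyte genes were high in both kinds of oligodendrocyte culture, with mean signals of Gfap of 16237 and 15744 against 80.7 in progenitors, although PDGFRα selection would remove astrocytes at the start. Loss of 5′ signal on progenitor replicates 1 and 4 is argued against by a median log2 difference of 4.62 with only progenitor replicates 2 and 3, against 4.49 with all, and the list was lowest on replicate 2, whose spike-in ratios were the highest of the progenitors. All 13 of 13 measured genes were at least 2-fold higher in both kinds of culture, as astrocytes in the cultures would give. Of these genes 7 also reached a mean signal of 200 in progenitors and 0 were on another list. Progenitors that turned into astrocytes would give the same values, so the 2 sources cannot be told apart on arrays of whole cultures.

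Progenitor replicate 2 stood apart from the other progenitors, with cell cycle genes at a mean log2 signal of 10.3 against 12.28 to 12.54 and Enpp6 at 6560.5 against 45.5 to 333.9. A mislabelled oligodendrocyte culture like those measured here is argued against by an astrocyte gene level 4.55 log2 units under the lowest oligodendrocyte array, a difference of -4.55. RNA of such a culture mixed in would need a share of 22.4% to give its Mag signal, but the median of 8 bright astrocyte genes was 1.8% of their oligodendrocyte level, with exceptions in Aldoc at 37%, which the other progenitors shared, and S100b at 58.3%. Better labelling of long transcripts is argued against for the cell cycle genes, at -1.97 from the lowest other progenitor array, but it cannot be told apart for markers of newly formed oligodendrocytes, 1.64 ± 0.36 (SE over genes) above replicate 3, since the dap and thr spike-in ratios were also lower there, 0.223 and 0.195 against 0.375 and 0.36. The astrocyte gene level cannot decide on a mislabelled culture low in astrocyte genes, since every oligodendrocyte array was high in them. The design gives no biological explanation for a single replicate and none was tested, so its source stays open.

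Further genes set progenitor replicate 2 apart. Its signal was above the other progenitor arrays for Myrf, at 6848.4 against 752.1 to 1135, Rab33a, at 11355.5 against 1880.5 to 2262.2, Nkx2-2, at 12128.3 against 2735 to 3237.3, and St18, at 490.9 against 20.3 to 43.4. The same held for Fa2h, at 3046.8 against 182.8 to 495.9, Bmp4, at 3614.3 against 10.5 to 120.5, Plppr1, at 5738.8 against 2364.3 to 2912.2, and S100b, at 5650.9 against 501.5 to 700.6. Col9a1 was at 3911 against 971.1 to 1116.9 and Fam163a at 102.4 against 3.8 to 5.4. Lower on that array were Cspg4, at 1130.6 against 3505.6 to 3850, and Acan, at 26.8 against 42.9 to 46.1, where all 4 signals are under the floor of 100 and the difference is within background. Mean log2 signals of lists were 11.98 against 11.49 to 11.51 for cholesterol synthesis, 9.086 against 9.996 to 10.13 for p53 and apoptosis, and 11 against 12.56 to 12.69 for Schwann cell markers.

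Control oligodendrocyte replicate 3 was above the other control arrays for Rab33a, at 8401.3 against 6316.1 to 6600.3, Ano4, at 1641.5 against 415 to 567.3, Gjb1, at 3380.4 against 197.4 to 540.8, Nefm, at 927.1 against 117.9 to 248.5, and Rad51ap1, at 462.6 against 98.4 to 127.9. It was below them for Tmem163, at 1646.4 against 4278.6 to 4653.4. Progenitor replicate 3 had Mobp at 751.3 against 18.9 to 69.9 and Mal at 81.2 against 4 to 17, all of the latter under the floor, and progenitor replicate 4 had Aldoc at 3646 against 4297.6 to 4429.3. Control probe sets for ribosomal RNA, which entered no comparison, were above all oligodendrocyte arrays on progenitors, except the 3′ probe set on replicate 2, at 207.1. The 5′ probe set gave 7805.8, 2109.7, 2357 and 6983.1 on progenitor replicates 1 to 4 against at most 130.4, and the 3′ probe set 5977.8, 954.2 and 3790.6 on replicates 1, 3 and 4 against at most 239.9.

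Other splits of the arrays were tried for each count, 35 per comparison. With 35 splits no share can be smaller than 1 of 35, and no correction was made for the several counts tested. For knockout against control oligodendrocytes 1 of 35 splits, the real one, gave as many as 758 genes and the highest other gave 5. That share, under 0.05, argues against chance over these splits, which ignore the assumed pairing, but cannot exclude it. Of the 8 splits that part all 3 pairs, the highest other gave 1 gene and 9 lists, and 8 splits are too few for a share under 0.05. The split with 5 genes set knockout replicate 3 with control replicates 3 and 4 and parted none of the pairs. For control oligodendrocytes against progenitors it was 1 of 35, with 5433 genes against 685 at most, which argues against chance within the same limit. For knockout oligodendrocytes against progenitors it was also 1 of 35, with 5098 genes against 4659 in the split that set progenitor replicate 2 with the knockout arrays. That split points to a structure of the samples, and the next highest gave 612. For the counts of gene lists the share was not under 0.05, so the splits do not argue against chance there. As many as the 9 lists of knockout against control came from 2 of 35 splits, with 9 in the highest other. As many as the 8 lists of control oligodendrocytes against progenitors came from 3 of 35, with 8 in the highest other, and as many as the 6 of knockout oligodendrocytes against progenitors from 12 of 35, with 8 in the highest other.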

How the results depend on the processing

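The settings with only progenitor replicates 2 and 3, and without control replicate 3 in a fit on 2 groups, were chosen after seeing the data. So were another division of the arrays for the share and a share without the astrocyte list. For knockout against control oligodendrocytes, 758 genes became 2160 with array weights, 1587 when only the 2 groups were fitted, 1436 when control replicate 3 was also left out, 341 at an adjusted p under 0.01 and 374 to 670 without any one replicate. A replicate block, which follows the assumed pairing in that comparison and leaves out the progenitors and control replicate 4, gave 2238 genes. Since the fit on the 2 groups alone gave 1587, the part due to the block was not separated. Both settings leave out the spread among progenitors, whose median gene SD was 0.388 against 0.2 among knockout and 0.224 among control arrays. Among named genes and lists the block setting also changed the calls of Myrf, Opalin, Ugt8a, Olig2, S100b, Pmp22 and the adhesion list, and no other. Of these, Myrf, Opalin, Ugt8a and S100b passed in the fit on 2 groups as well. For control oligodendrocytes against progenitors, 5433 became 9899 when every probe set was tested by itself, 2908 with a 2-fold minimum and 4616 to 6119 without any one replicate. For knockout oligodendrocytes against progenitors, 5098 became 9388, 2971 and 3951 to 5917 in the same order. In the comparisons with progenitors the numbers were not taken as pairing the samples (r from -0.0687 to 0.193 and from -0.117 to 0.033), and a block gave 4661 and 3091 genes. The stricter thresholds, the 2-fold minimum and the testing of more probe sets account for their counts by construction, and for the others the cause was not tested. The lists past the threshold numbered 9, 8 and 6 in the same order of comparisons. With an estimated correlation 0, 1 and 1 lists passed, with fry 5, 11 and 8, and without any one replicate 8 to 9, 7 to 8 and 6 to 8. Between knockout and control oligodendrocytes the lists of myelin proteins (fry, adjusted p = 0.00174), genes that oppose differentiation (0.00384), neuronal markers (0.00384), progenitor markers (0.0178) and cholesterol synthesis (0.0411) passed with fry. Those of cell cycle (0.143), sphingolipid synthesis (0.143), adhesion (0.18) and astrocyte markers (0.0568) did not. The share of induced genes, 92.7%, became 86.77% with a 2-fold minimum and 85.35% to 94.96% without any one replicate. The share of repressed genes, 94.1%, became 97.92% with a pseudocount of 64, 96.55% with quantile normalization, 100.5% with the mean of probe sets, 89.68% with a 2-fold minimum, 102.1% as a ratio of means, 114.3% when chosen and measured on all control arrays, 88.57% with another division and 90.88% to 108.7% without any one replicate. Choosing and measuring on the same arrays lets chance in those arrays into the share, and for the other moves the cause was not tested. Without the 13 measured genes of the astrocyte list the shares were 91.8% and 94.1%. Genes outside that list, such as Apoe and Mlc1, were not left out.

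Single genes that turned direction did so as follows, on the log2 scale, and the cause was not tested. Between knockout and control oligodendrocytes H2-K1 went to 0.18 with a pseudocount of 64 and 0.17 with quantile normalization. Between control oligodendrocytes and progenitors Sox10 went to 0.65 with the mean of probe sets and Cnp to -0.0758 with only progenitor replicates 2 and 3. Between knockout oligodendrocytes and progenitors, quantile normalization took Olig2 to 0.0105 and Sox10 to 0.21, and the mean of probe sets took Sox10 to 1.27 and Qdpr to 0.19, with Qdpr at 0.97 without shared probe sets. Without any one replicate Mag ranged from -0.93 to 0.60, above 0 without knockout replicate 3 (0.52) or progenitor replicate 2, Cnp from -0.0883 to 0.36, below 0 without progenitor replicate 1, and Mog from -0.0755 to 0.98. With only progenitor replicates 2 and 3 the values were -0.29 for Cnp, -0.83 for Mog, -0.28 for Myrf, -0.0346 for Ugt8a and -0.0429 for Opalin. The values of Mog here are within background, since every knockout and progenitor array lay under 100. Over all named genes and alternatives chosen beforehand, 4610 values kept direction and side of the threshold, 178 fell short of it, 36 newly passed it and 12 turned. For the alternatives added later the numbers were 153, 23, 2 and 6. Signal over background limits dim genes: a fold is a lower bound where every array of the lower group lay under 100, and where only their mean did, the fitted fold depends on the pseudocount. Genes near the highest signal of an array, such as Mbp and Cnp, are limited by the top of the scale.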

Other observations

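The gene set in this part was put together after the values of Matn1, Col2a1, Acan and its other genes had been seen. No explanation was tested on it, and its counts are no independent support. Of 12 measured genes for cartilage matrix proteins, their sulfation and the transcription factor Sox9, 10 were higher in knockout than in control oligodendrocytes at limma's threshold, 0 were lower and 2 did not pass. The 10 include the 3 genes that prompted the set. Besides those 3 genes, the collagen Col9a1 was 6.87-fold higher, at a mean signal of 8691 against 1541 (limma, adjusted p = 0.0159), or 4.56-fold without control replicate 3. Without that array the fold of Col2a1 was 7.62. Col11a2 was 5.53-fold higher (adjusted p = 0.0039), Col9a3 4.71-fold (0.000304), Col11a1 3.64-fold (0.0132) and the sulfotransferase Chst11 2.96-fold (0.0124). In progenitors Col11a1 and Chst11 had means of 10649 and 5762, near the knockout means of 12553 and 5355, while the control means were 3725 and 1826. Col9a1 had 1750 in progenitors, also above its control mean. The other genes of the set that passed had lower means in progenitors than in control cultures. Sox9, which acts in cartilage and glia, was 1.71-fold higher without passing (adjusted p = 0.491), as was Matn4, 1.93-fold (0.329). Of the 3 measured smooth muscle and pericyte genes, Tagln and Myl9 were also higher, 6.00-fold and 3.36-fold, but neither passed without any one knockout array, and Acta2 did not pass.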
